A study of Homo sapiens with 18 samples.

How the data were processed

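RNA of MOLM-13 cells was sequenced as 75 bp paired-end reads, per the labels' protocols. The submitters' processing notes name STAR 2.7.1b, SAMtools 1.9, deepTools 3.3.2, bedtools 2.29.0, MACS2 2.1.4 and the build GRCh38, without roles or settings. The deposited files are 12 broad-peak tables, a forward and a reverse strand file for each of 6 peak lists, called per library letter and not on pooled replicates. Per the labels, the 2 WT lists come from the wild-type click libraries A and B, each against 1 DMSO library; the knockdown lists are attached to the METTL3-KD and METTL16-KD control libraries A and B, and the list names join WT with the knockdown, but their counterpart library is not given in the sources used here. The other samples were not analysed here. Replicates are separate libraries by label; whether they came from separate cultures is not given, so spread between A and B may be technical.

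The deposited fold enrichment of a peak is a ratio between its 2 libraries, as MACS2 writes it, averaged by the authors' caller over the broad peak. The deposited −log10 p and −log10 q columns are likewise averages over the peak. About 45% to 53% of peaks per condition have a −log10 q below 1. The lowest deposited −log10 p, averaged over the lists of a condition, is 2.10 in WT, 2.63 in METTL16-KD and 3.13 in METTL3-KD. The lists thus reach down to different lowest values, in the order of list length. The deposited score is 10 times the −log10 q truncated to a whole number and was not used further. These values were used only to rank, describe or filter peaks within a list. The files hold no counts, coverage or library sizes, so depth per sample is unknown and cannot be separated from differences in list length: a deeper library gives more peaks from the same RNA.

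Both strand files of a list were joined into 1 set, 129656 peaks in all. The reference table gives RefSeq gene spans on GRCh38.p14 with symbol and biotype, but no strand and no exons; the planned split into exons, introns, untranslated regions and antisense sequence, and the sense-strand assignment of genes, could therefore not be made. Each peak was assigned to the gene span sharing most bases, with ties to protein-coding and then shorter genes; 88.2% of peaks had a gene and 13.3% of those overlapped several, which makes their assignment uncertain, as it is for near-identical copies such as ribosomal RNA genes and pseudogenes. The forward file was taken as the plus strand after a check on 37 genes of known strand, where 1098 of 1182 peaks (92.9%) matched. A gene said to have no peak has none assigned to it, and a peak over it can count for another gene. Coordinates are printed 1-based.

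A peak of list A was called reproduced when it shared at least 1 bp on the same strand with a peak of list B of its condition. Reproduced WT peaks were compared with the peaks of either list of a knockdown. Each share was set against the same peaks moved to random positions within the gene holding them, 1000 times. Gene sets were genes with a reproduced peak, tested by Fisher's exact test among the 12552 genes with a peak in any list. For 18 gene lists fixed before the data were examined, members with a reproduced peak were tested in the same way with Benjamini-Hochberg adjustment, and against 10000 random lists matched on gene length in 10 bins. Genes are not independent replicates, and these tests describe these lists. Per-list measures were compared by exact permutation of 2 lists against 2, whose smallest p is 0.33. Positions within genes used every peak wholly inside a protein-coding gene, counted from the 5′ end by the strand of the file. Peaks running over a gene edge drop out, so each list was compared with its own peaks moved at random within their genes. Reproduced peaks of A and B are largely the same regions and were not used as replicates for position.

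The genes named were fixed by rule before the data were examined: per condition the 10 genes with the highest mean over A and B of their highest −log10 q among genes with a reproduced peak, the 5 with most reproduced bases and up to 5 members of each gene list; for each pair of conditions the 8 highest-ranked in both, and for the knockdowns the 8 highest-ranked in one and not in the other; and always METTL3, METTL16, MAT2A and MALAT1. Not every gene under the rule is printed.

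Alternatives changed the peak threshold, the overlap required, strand, direction, list length, background, gene assignment, feature rule and the replicate left out. On simulated lists with 60.8% of 8000 peaks copied with a small shift the overlap step gave 61.7%, and peaks redrawn within genes differed from random moves by −0.0773 percentage points. Simulated peaks placed at random differed from random moves by −0.128 percentage points in the last part of the gene, and with 7.89 points planted there 7.88 were measured, for 8000 peaks. Of random lists drawn from the 12552 genes with a peak, 5% passed an exact test at p = 0.05 against the genes with a METTL16-KD peak. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.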

Results

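The series applied meCLICK-Seq, in which a small-molecule surrogate takes the place of the methyl group that RNA methyltransferases transfer and the tagged RNA is degraded by click chemistry, to MOLM-13, an established acute myeloid leukaemia cell line. The 18 samples comprised click-treated and control libraries of wild-type cells, of cells with an inducible short hairpin RNA against METTL3 and of cells with one against METTL16, with 2 libraries (A and B) per group, 1 wild-type DMSO library, and antibody-based m6A libraries with their input. METTL3 is the catalytic subunit of the main m6A writer complex of messenger RNA, and METTL16 is a separate m6A methyltransferase. Hairpins had been induced with 200 ng/mL tetracycline for 3 days (METTL3) or 2 days (METTL16). The values analysed were broad peaks in files attached to 5 of these samples, which form 6 peak lists: A and B for wild type (WT), METTL3-KD and METTL16-KD. Each WT list sets a wild-type click library against the same DMSO library, so the 2 WT lists are not independent. The labels attach each knockdown list to the control library of that knockdown and letter. Their names join WT with the knockdown, and which wild-type or other library served as counterpart is not given. Which library served as the enriched one is not given in the sources used here, so a peak marks a region of unequal coverage and its direction is not read. The lists carry no read counts, and sequencing depth is unknown.

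The gene targeted by each hairpin was examined first. METTL3 (chromosome 14) carried 2 peaks in METTL3-KD list A and 1 in METTL3-KD list B, and no peak in either WT list or either METTL16-KD list. The METTL3 peak shared by A and B spanned positions 21500045 to 21501007 in A, with a fold enrichment of 2.59 and a −log10 q of 1.93, and had a fold enrichment of 2.11 and a −log10 q of 0.339 in B. METTL16 (chromosome 17) carried 7 peaks in WT A, 6 in WT B and 5 in METTL16-KD A, and none in METTL16-KD B or in either METTL3-KD list. Fold enrichment at METTL16 lay between 2.62 and 3.99 in WT A. These peaks locate coverage differences over the genes and do not measure how far either transcript was depleted.

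**Figure D1:**
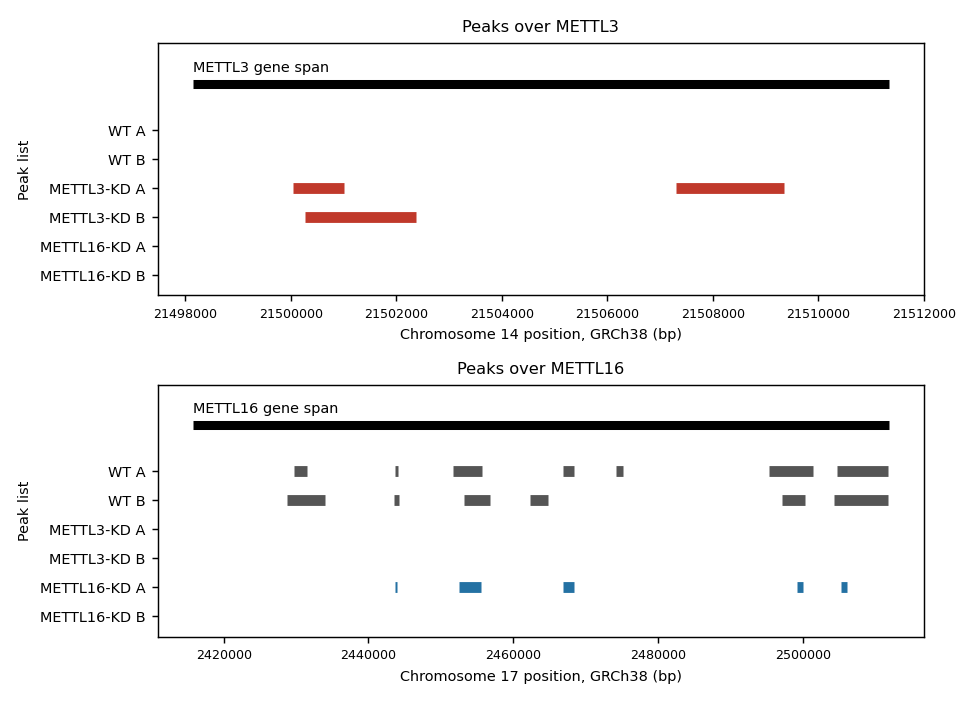
Peaks of the 6 lists (rows; bars to scale) over the gene spans of METTL3 on chromosome 14 and METTL16 on chromosome 17, with GRCh38 positions in bp on the x axes. METTL3 has peaks in the METTL3-KD lists and in none of the other lists, and METTL16 has peaks in both WT lists and in METTL16-KD A.

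Comparison of click-treated wild-type cells with DMSO asks where in the transcriptome coverage changes after the click reaction. The DEAD-box RNA helicase gene DDX39B held the highest-ranked WT peak (chromosome 6, 31530964 to 31532639), with a fold enrichment of 132 in A and 125 in B. Peaks with high fold enrichment also lay over the leukocyte inhibitory receptor gene LILRB1 (chromosome 19, 54637305 to 54638018; 56.1 in A and 68.0 in B) and over the long non-coding RNA gene LOC105375855 (chromosome 8, 57481685 to 57492722; mean 11.9 ± 0.157, SD, n = 2). The granule serine protease genes PRTN3 and ELANE, adjacent on chromosome 19, had a mean −log10 q of 123 ± 1.36 (SD, n = 2) and 89.1 ± 1.12, at a fold enrichment of 2.24 and 2.28. Ribosomal RNA loci (RNA45SN1, RNA18SP5 and the pseudogene LOC110467529) were also among the 10 highest-ranked WT genes, together with PLXNB2, GOLGA8T, LYPLA2P1 and RBFOX2; placement among near-identical ribosomal RNA copies and pseudogenes is uncertain. The most bases under reproduced WT peaks fell in long genes: ADK (adenosine kinase) with 40 reproduced peaks covering 295 kb, PVT1 (a long non-coding RNA gene beside MYC) with 20 peaks over 200.3 kb, NCAM2 with 33 over 185 kb, PITPNC1 with 19 over 185 kb, and SLC39A11 with 31 over 182 kb.

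WT lists held 40059 ± 126 peaks (mean ± SD, n = 2 lists), METTL16-KD lists 17037 ± 2425 and METTL3-KD lists 7732 ± 15.6. WT lists were thus 5.18 times as long as METTL3-KD lists and 2.35 times as long as METTL16-KD lists. List lengths were not adjusted for the unequal lowest −log10 p of the lists. Each difference exceeded the spread between A and B, but an exact permutation test of 2 lists against 2 cannot go below p = 0.33. The peaks covered 104 ± 1.47 Mb in WT, 29.8 ± 5.66 Mb in METTL16-KD and 10.8 ± 0.322 Mb in METTL3-KD. Of the WT A peaks 72.8% shared at least 1 bp on the same strand with a WT B peak, compared with 57.5% for METTL16-KD and 33.6% for METTL3-KD. From B to A the shares were 72.2%, 71.2% and 33.7%. Both WT lists use the same DMSO library, so part of their agreement is built in, random moves do not remove that part, and the WT shares are no measure of how much better WT peaks reproduce. Among peaks lying inside a gene the shares were 73.6%, 58.2% and 32.0%. After random moves within the gene they averaged 32.0%, 14.2% and 9.07%, and none of 1000 moves reached the observed share in any condition (one-sided permutation p = 0.000999, the smallest that these moves allow). The moves treat every position of a gene span alike, without regard to exons or to where reads can be placed. An excess over them therefore does not show what the peaks mark. The opposite strand was met by 5.04% of WT, 1.69% of METTL16-KD and 1.83% of METTL3-KD peaks. The lower share in METTL3-KD was found in every range of −log10 q: below a −log10 q of 1 it was 20.9% in METTL3-KD (95% Wilson interval 19.7 to 22.2), 38.5% in METTL16-KD (37.4 to 39.6) and 54.6% in WT (53.9 to 55.3), and from 5 to 20 it was 73.0% (68.5 to 77.1), 91.9% (90.0 to 93.5) and 98.6% (98.0 to 99.0). These intervals cover counting error only.

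**Figure D2:**
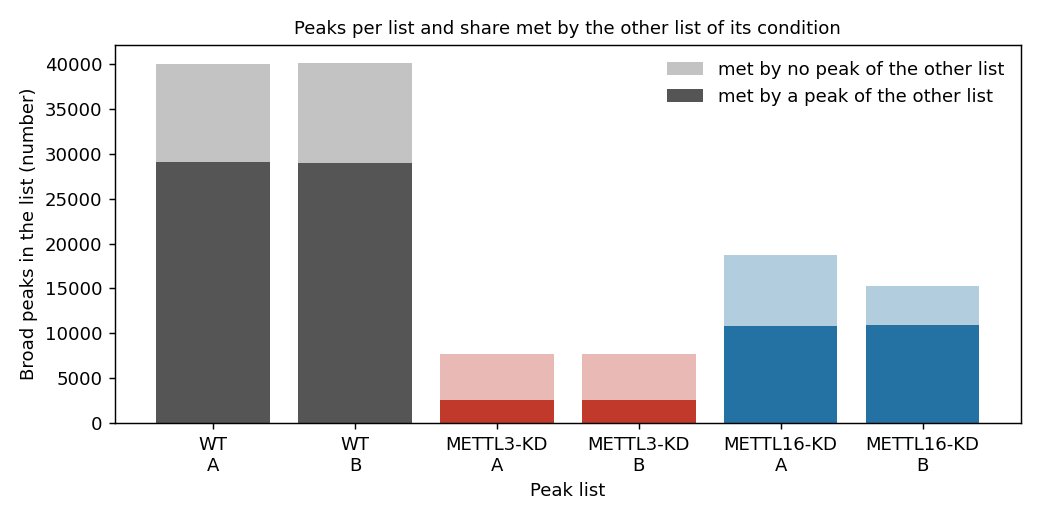
Number of broad peaks (y axis) in each of the 6 lists (x axis); the dark part of a bar is the peaks met on the same strand by the other list of the condition, and the pale part is the rest. WT lists average 40059 peaks, and the dark part is 72.8% of WT A, 33.6% of METTL3-KD A and 57.5% of METTL16-KD A.

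Setting METTL3-KD beside WT asks how far the regions in the METTL3-KD lists coincide with those in WT. As the counterpart library of the METTL3-KD lists is not given, a shared region is not read as one that persists after depletion. Of 29085 reproduced WT peaks, 7437 (25.6%) were met by a peak in either METTL3-KD list; for those inside a gene the share was 25.1%, against 10.1% after random moves (one-sided permutation p = 0.000999). Conversely, 84.2% of the 2597 reproduced METTL3-KD peaks shared a base with a WT list. Genes ranked high in both conditions included LOC105375855, the plexin receptor gene PLXNB2, ELANE, GOLGA8T and ribosomal RNA copies. At PLXNB2 (chromosome 22, 50276269 to 50276629) METTL3-KD fold enrichment was 3.39 in A and 2.53 in B, and at ELANE 1.47 and 1.43. Other highly ranked METTL3-KD genes were the splicing factor gene SRSF6 (chromosome 20, 43458430 to 43459582; 2.50 and 1.95), TSPOAP1 (2.73 and 2.17) and HERC2P2. The most bases of reproduced METTL3-KD peaks lay in PVT1 with 31.2 kb, P2RY8 with 30.8 kb, LOC105375855 with 27.1 kb, GAS6 with 26.6 kb and MIR3667HG with 24.0 kb. In all, 1559 of the 1753 genes with a reproduced METTL3-KD peak also had a reproduced WT peak (odds ratio 3.80, 95% interval 3.26 to 4.44; Fisher's exact test, two-sided, p = 4.41e-84, across genes, which are not independent replicates).

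The METTL16-KD lists were set beside WT in the same way. Of the reproduced WT peaks, 16907 (58.1%) were met by a METTL16-KD peak; for those inside a gene the share was 59.5%, against 20.9% after random moves (one-sided permutation p = 0.000999), and 97.4% of the 10783 reproduced METTL16-KD peaks shared a base with a WT list. Genes ranked high in both included DDX39B, LOC105375855, PRTN3 and GOLGA8T. In METTL16-KD the PRTN3 peak (chromosome 19, 843979 to 847699) had a fold enrichment of 1.53 in A and 1.57 in B, and the DDX39B peak 1.92 and 1.81. CLEC11A, which encodes a haematopoietic growth factor, was among the 10 highest-ranked METTL16-KD genes (chromosome 19, 50723470 to 50724824; 3.62 and 3.24), as were MYO15B (4.78 and 5.21) and the long non-coding RNA gene BALR6 (12.2 and 13.1). The most bases lay in NCAM2 with 36 reproduced peaks over 132 kb, BALR6 with 17 over 110.0 kb, PITPNC1 with 18 over 101 kb, AFF3 with 27 over 95.2 kb and ARHGEF18 with 7 over 89.6 kb. WT and METTL16-KD shared 3955 genes out of 4083 with a reproduced METTL16-KD peak (odds ratio 22.1, 95% interval 18.5 to 26.5, over genes), where 2891 would be shared by independent gene sets of these sizes.

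WT peaks were met more often by METTL16-KD than by METTL3-KD, a difference of 32.6 percentage points over reproduced peaks. In lists of the same letter, 36.5 ± 5.05% of WT peaks (SD, n = 2) were met by METTL16-KD and 14.2 ± 1.79% by METTL3-KD, a gap larger than the spread between A and B (exact permutation test, smallest possible p = 0.33). Without replicate B this same-letter gap was 27.1 points and without replicate A 17.4, over all peaks of the remaining WT list. With the 7721 highest-ranked peaks of every list the shares were 75.7% and 50.9%, so a gap was present at equal list length.

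**Figure D3:**
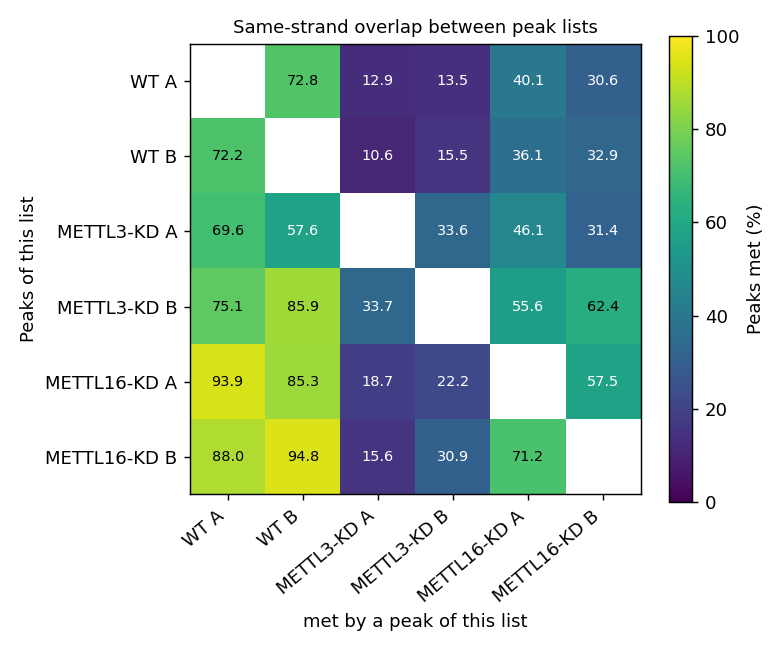
Share (%) of the peaks of each list (rows) that are met on the same strand by a peak of each other list (columns), by colour and printed value. METTL16-KD lists are met by WT lists at 85.3% to 94.8%, and METTL3-KD lists are met by each other at 33.6% and 33.7%. The longer METTL16-KD lists meet METTL3-KD lists at 31.4% to 62.4%.

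The METTL3-KD and METTL16-KD lists were compared to find genes marked in both knockdowns. METTL3-KD B peaks were met more often by METTL16-KD A and B (55.6% and 62.4%) than by METTL3-KD A (33.7%). METTL3-KD A peaks were met at 46.1% by METTL16-KD A, 33.6% by METTL3-KD B and 31.4% by METTL16-KD B. The METTL16-KD lists are longer, which raises their shares, so these values do not separate condition from list length or letter. Reproduced peaks in both were found for 1211 genes, which is 69.1% of the METTL3-KD genes and 29.7% of the METTL16-KD genes (odds ratio 6.17, 95% interval 5.53 to 6.88; Fisher's exact test, two-sided, p = 1.16e-253, over 12552 genes with any peak). Independent sets of these sizes would share 570 genes; libraries common to the lists would add to the excess, which cannot be simulated from peak lists. The odds ratio was 5.18 without replicate A and 2.60 without replicate B. The highest-ranked genes in both were ribosomal RNA copies, LOC105375855, SRSF6, TSPOAP1 and MYO15B. Genes ranked high in METTL3-KD without a reproduced METTL16-KD peak were PLXNB2, PDE3A (a cyclic nucleotide phosphodiesterase), CCSER1, the myeloid adhesion receptor gene ADGRE3, DTWD2, the RNA helicase gene DDX5, RNA28SN2 and RNA28SN3. The DDX5 peak (chromosome 17, 64498940 to 64500714) had fold enrichments of 2.18 and 1.97, the ADGRE3 peak (chromosome 19, 14622347 to 14623053) 2.06 and 1.88, and the PDE3A peak (chromosome 12, 20551250 to 20553389) 1.88 in both lists. Genes ranked high in METTL16-KD without a reproduced METTL3-KD peak were PRTN3, CLEC11A, ERBB4 (a receptor tyrosine kinase), ZEB2 (a zinc-finger transcription factor), PAM16, EEF1A1P13, RNA18SP5 and HFM1. ERBB4 (chromosome 2, 211703249 to 211704392) had fold enrichments of 19.9 and 22.5, and HFM1 (chromosome 1, 91387092 to 91387533) 11.4 and 6.81.

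Protein-coding gene spans held 80.3 ± 0.00506% of peak bases in WT (SD, n = 2), 80.0 ± 0.276% in METTL16-KD and 71.6 ± 2.33% in METTL3-KD. Bases in both kinds of span were counted as protein-coding. The parts of long non-coding RNA gene spans outside protein-coding spans held 6.26 ± 0.0626%, 7.17 ± 0.183% and 10.2 ± 0.814%. Outside annotated genes lay 11.7 ± 0.0510%, 10.8 ± 0.126% and 14.2 ± 1.95%. The METTL3-KD share in protein-coding spans was below those of WT and METTL16-KD by more than the spread between lists (exact permutation test, p = 0.33, the smallest possible). Exons, introns and untranslated regions could not be assigned, because the gene table used gives spans only. Position within protein-coding genes, a measure chosen after the data were seen, was also compared. Of METTL3-KD peaks lying wholly inside a gene, 15.5% in A and 10.7% in B had their centre in the final 10% of the gene span (13.1 ± 3.40%, SD, n = 2), compared with 8.28 ± 0.0158% in WT and 7.47 ± 0.216% in METTL16-KD (exact permutation test, p = 0.33 for both, the smallest possible). The same peaks moved at random within their genes gave 8.16% for METTL3-KD A and 8.75% for METTL3-KD B, so both lists lay above random placement (two-sided permutation p = 0.000999 for each). The WT lists did not differ detectably from random placement (8.31% in A and 8.29% in B; permutation p = 0.889 and 0.906). Both METTL16-KD lists lay below it (8.93% in A and 9.02% in B; permutation p = 0.000999 for each). The difference of METTL3-KD from WT was 7.18 points without replicate B and 2.39 without replicate A, so its size rests largely on A. In genes over 100 kb the shares were 16.5 ± 7.53% in METTL3-KD, 9.22 ± 0.0380% in WT and 7.75 ± 0.00494% in METTL16-KD. In genes under 20 kb they were 5.30 ± 0.464%, 4.82 ± 0.0842% and 5.93 ± 0.0961%.

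**Figure D4:**
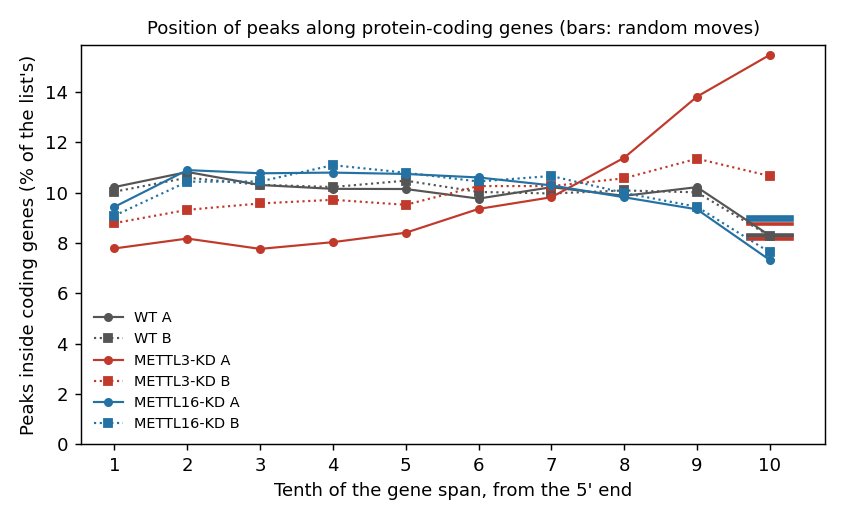
Share (%) of the peaks lying wholly inside a protein-coding gene (y axis) in 10 equal parts of the gene span from the 5′ end (x axis), with 1 line per list (circles and solid lines A, squares and dotted lines B); short bars in the last part give the mean of random moves within genes for each list. METTL3-KD A reaches 15.5% and METTL3-KD B 10.7% in the last part, where the random moves lie between 8.16% and 9.02%.

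Gene lists fixed before the data were examined were then tested, with 48 tests over 16 lists that had any member with a peak and 3 conditions, adjusted by the Benjamini-Hochberg method. Members are counted out of those with a peak in any peak list, and not out of the full gene list. The acute myeloid leukaemia driver and KMT2A fusion programme, relevant because MOLM-13 carries a KMT2A fusion, had a reproduced METTL16-KD peak in 22 of 28 members (odds ratio 7.64; Fisher's exact test, adjusted p = 3.52e-05), against 4 of 28 in METTL3-KD and 25 of 28 in WT, neither of which passed. The highest-ranked members were ZEB2, the kinase gene CDK6, the transcription factor gene RUNX1, SPI1 and PBX3. In METTL16-KD, ZEB2 (chromosome 2, 144481090 to 144484787) had fold enrichments of 6.80 and 6.18 and CDK6 (chromosome 7, 92769059 to 92770947) 5.81 in both lists. Members with a reproduced METTL3-KD peak included RUNX1 and FLT3. Against random lists matched on gene length the METTL16-KD count stayed above expectation (mean 12.4 of 28, permutation p adjusted 0.0384). Matching on expression was not possible, as the files hold no read counts, so its part in this excess is not known. The call was lost when a peak in either list sufficed (Fisher's exact test, adjusted p = 0.0602), at −log10 q of at least 5 (adjusted p = 0.136, exact test; odds ratio still 6.21, with 6 members left) and without replicate B (odds ratio 3.97, adjusted p = 0.0521, exact test). Over all alternatives the adjusted p ran from 2.27e-05 to 0.136 (exact tests). Of its WT genes, 22 of 25 also had a reproduced METTL16-KD peak, compared with 44.5% of all WT genes (odds ratio 9.19, Fisher's exact test, adjusted p = 0.000263). This comparison was not matched on gene length or expression.

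Chromatin remodellers and histone methyltransferases had a reproduced peak in 19 of 26 members in METTL16-KD (odds ratio 5.65; Fisher's exact test, adjusted p = 0.000637) and in 25 of 26 in WT (odds ratio 10.3; Fisher's exact test, adjusted p = 0.0332). In METTL3-KD the single member was the histone demethylase gene KDM2A. Examples in METTL16-KD were the histone methyltransferase gene KMT2C, with fold enrichments of 5.57 and 4.85, and the nucleosome remodeller gene BPTF, with 4.22 and 5.02. Members of this list are long genes, and neither count passed against length-matched random lists (permutation p adjusted 0.24 for both). The METTL16-KD odds ratio was 4.47 without replicate A and 10.4 without replicate B, and its call was lost at q of at most 0.05 (Fisher's exact test, adjusted p = 0.173). At −log10 q of at least 5 the sign turned in both conditions, but few members had any peak there and neither departure passed adjustment. At that threshold 0 members had a reproduced METTL16-KD peak and 3 a WT peak, −14.1 and −18.0 points from the share of all genes (14.1% and 60.9%). The WT call was lost at q of at most 0.05 (Fisher's exact test, adjusted p = 0.110), with an odds ratio still at 4.38 and 22 members left. With 1 WT list left out it cannot be judged, as 96.0% (without A) and 93.2% (without B) of all genes then have a peak and 26 of 26 members would not pass. Of 26 translation factors, 18 had a peak in any list. Each of these 18 had a reproduced WT peak (Fisher's exact test, adjusted p = 0.0369, and length-matched permutation p adjusted 0.0624), PABPC1 and EEF1D ranking highest, with 5 in METTL3-KD and 9 in METTL16-KD. This call was also lost at q of at most 0.05 (Fisher's exact test, adjusted p = 1), and with 1 WT list left out it cannot be judged for the same reason. At −log10 q of at least 5 its sign turned, but this departure did not pass adjustment. There 5 members had a reproduced peak, −5.32 points from the share of all genes (60.9%). Among genes with a reproduced peak in a single knockdown, 2872 had it in METTL16-KD and 542 in METTL3-KD. The leukaemia programme and the chromatin list each had 18 such members in METTL16-KD and 0 in METTL3-KD, the most uneven split possible (Fisher's exact test, p = 0.0970, adjusted p = 0.776 for each). No list could thus pass this test towards METTL16-KD, and it does not show whether any list differed between the knockdowns in that direction.

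The other lists did not pass after adjustment. Myeloid and monocytic markers had a reproduced peak in 13 of 16 members in WT, 8 in METTL16-KD and 6 in METTL3-KD, among them ELANE and the granulocyte receptor gene CSF3R (1.68 and 1.83 in METTL3-KD). The METTL3-KD count did not pass adjustment (odds ratio 3.71; Fisher's exact test, p = 0.0168, adjusted p = 0.116). Cytosolic ribosomal protein genes had one in 34 of 47 in WT, 8 in METTL16-KD and 1, RPL30, in METTL3-KD (odds ratio 0.133; Fisher's exact test, p = 0.0111, adjusted p = 0.106), a count that passed without replicate A. Writers, erasers and readers of m6A had 16 of 19 in WT, 9 in METTL16-KD and 5 in METTL3-KD (METTL3, WTAP, YTHDC2, IGF2BP2 and HNRNPC), and the demethylase gene FTO had fold enrichments of 8.38 and 6.80 in METTL16-KD. Genes of the methionine cycle had 13 of 15 in WT, 7 in METTL16-KD and 0 in METTL3-KD. Transcripts reported to depend on METTL3 in leukaemia had 8 of 8 in WT, 4 in METTL16-KD, among them MYB and ITGA4, and 1, the integrin gene ITGA4, in METTL3-KD. Splicing factors of the SR and hnRNP families had 17 of 24, 11 and 5 in WT, METTL16-KD and METTL3-KD, and genes of DNA damage and cell cycle had 13 of 16, 10 and 4. Stress response genes had 8 of 10, 4 and 1 in the same order, and nuclear long non-coding RNAs 6 of 7, 4 and 3. Mitochondrially encoded genes had 3 of 7, 2 and 2, and the joint list of small nuclear RNAs and abundant Pol III RNAs 2 of 3, 1 and 0. Among markers of other cell types, erythroid and megakaryocytic genes had no peak assigned in any list. Lymphoid markers had 2 of 3, 1 and 0 in the same order, and epithelial, hepatic and neuronal markers 1 of 2, 0 and 0. Reported METTL16 substrates, among them the methionine adenosyltransferase gene MAT2A, MALAT1 and U6 small nuclear RNA genes, had no peak assigned to them in any of the 6 lists. A peak over such a gene can count for another gene whose span shares more bases with it, so overlap with these genes is not excluded.

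**Figure D5:**
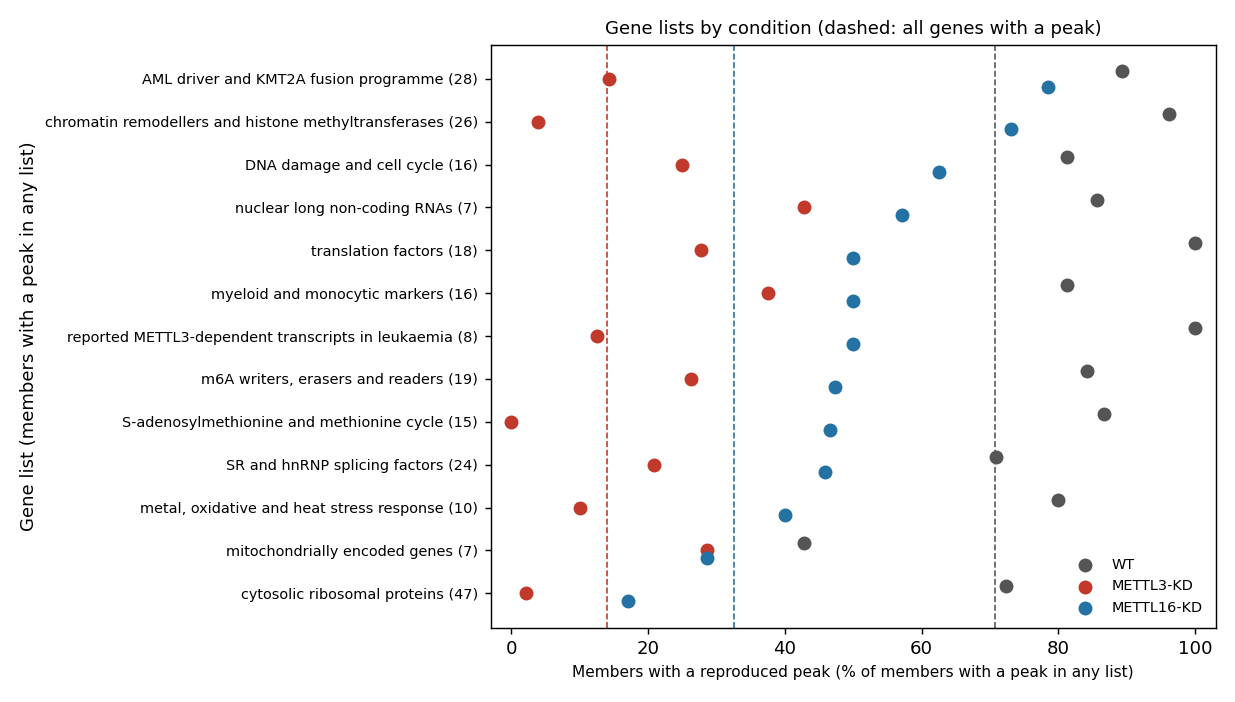
Members with a reproduced peak as a share (%) of members with a peak in any list (x axis) for the 13 fixed gene lists with at least 5 such members (rows, number in brackets), by condition (colour); dashed lines give the share over all genes with a peak. The leukaemia programme lies at 78.6% in METTL16-KD against 32.5% of all genes, and at 14.3% in METTL3-KD against 14.0%.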

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

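The position of peaks in genes and all tests of it in this part were chosen after the lists had been seen. Relative to random moves within genes, the share of peaks in the final 10% of the gene span was 7.31 points higher in METTL3-KD A and 1.91 in METTL3-KD B, and lay at −1.61 and −1.39 points in METTL16-KD A and B, a mean gap of 6.11 percentage points between the knockdowns; the 2 knockdowns departed from random placement in opposite directions, and with 1 spread estimated from all 6 lists the gap did not pass (t test on 3 residual degrees of freedom, p = 0.0695, 95% interval −0.907 to 13.1; exact permutation of 2 lists against 2 cannot go below p = 0.33). The SDs were unequal, 3.82 points in METTL3-KD, 0.157 in METTL16-KD and 0.000884 in WT, whose 2 lists share a library. The common spread of 2.21 lies below that of METTL3-KD, so this p and interval are likely too favourable. The opposite directions were measured over all peaks. For reproduced peaks outside WT no random moves were made, so a direction is not known. Of these, 18.0% of 256 in METTL3-KD and 17.2% of 157 in METTL16-KD lay in that part, against 15.6% and 7.04% of the other reproduced peaks (Fisher's exact test over peaks, p = 0.354 and 2.58e-05). Weak calls are argued against as the cause, since at a −log10 q of at least 2 the gap from WT was at least 5.25 points in both letters, and peak width is argued against as the whole cause, since random moves keep the widths and METTL3-KD still exceeded them by at least 1.91 points. A different choice of genes is argued against as the whole cause, since in genes with peaks in both conditions, with WT weighted to the METTL3-KD peaks of each gene, the gap from WT was 6.69 ± 0.492 points (SE over genes) in A and 2.56 ± 0.398 in B, about as before (7.18 and 2.39). Differences in depth or RNA quality between libraries cannot be tested from peaks and stay open, as does a biological explanation, an untested hypothesis: METTL3 places m6A largely near stop codons and in 3′ untranslated regions, so METTL3-dependent regions may lie towards gene ends, but exons and the enriched library are unknown here.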

How the results depend on the processing

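Alternatives restricted to q of at most 0.05, to main chromosomes without ribosomal RNA genes or to a WT gene background for gene lists, equal list lengths for reproduced peaks and shared genes, and those on peak position, were chosen after seeing the data. The excess over random moves held in 37 of 37 alternatives for reproduced peaks and for WT peaks met by a knockdown. The smallest difference was 8.01 percentage points. It was taken between the share of all peaks and the random mean of peaks inside a gene, so it is only approximate as an excess. The odds ratio for genes shared by the knockdowns stayed between 2.60 and 9.34. Comparing lists of the same letter only, as a replicate block, gave 14.2% (METTL3-KD) and 36.5% (METTL16-KD) of WT peaks met and a shared-gene odds ratio of 3.56, and changed no call. The difference between the knockdowns, 32.6 points over reproduced WT peaks, was 24.8 with reciprocal overlap and 21.3 at −log10 q of at least 5. It was 24.7 with the same number of peaks per list, 22.3 in the replicate block and 17.4 to 27.1 with a letter left out. The block is the mean of the left-out values, all over same-letter lists, and no separate check. No alternative for WT peaks met used only lists of different letters, so overlap built in by a shared library is not removed. Across letters METTL3-KD met 13.5% of WT A and 10.6% of WT B peaks, and METTL16-KD 30.6% and 36.1%.

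A −log10 q of at least 5 left 2904.5 WT, 396 METTL3-KD and 838 METTL16-KD peaks per list, and q of at most 0.05 left 16130.5, 2825 and 7232. Joining peaks within 500 bp moved nothing, as no peaks lay that close. The share of bases in protein-coding spans was 77.9% (WT), 59.7% (METTL3-KD) and 65.4% (METTL16-KD) at −log10 q of at least 5, 81.2%, 67.6% and 79.0% in the same order at q of at most 0.05, and 77.9%, 73.3% and 80.9% by peak centre. The final-10% gap of METTL3-KD from WT and METTL16-KD, 4.79 and 5.59 points, was 7.76 and 8.94 for reproduced peaks, where A and B are largely the same regions; without replicate A it was 2.39 and 3.03, and without replicate B 7.18 and 8.15.

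Of the 4 gene list calls in the report, 1 passed with a peak in either list (of 2 that could pass), 0 at −log10 q of at least 5 (where few genes remain), 1 at q of at most 0.05 and 1 without replicate B (of 2 that could pass). Without replicate A 3 calls passed, of which 2 were reported calls (of 2 that could pass) and the other was ribosomal proteins in METTL3-KD. With a peak in either list or a replicate left out, 93.2% to 96.0% of all genes have a WT peak, so the 2 WT calls could not pass there. Against genes with a WT peak the WT calls cannot be tested, and both METTL16-KD calls passed, 2 of 2. At −log10 q of at least 5 the share of members with a peak minus that of all genes was −5.32 points for translation factors in WT, and −18.0 (WT) and −14.1 (METTL16-KD) for chromatin remodellers. None of these departures passed adjustment. For the other changes the cause was not tested. Depth is unknown, so how far it limits these counts cannot be given.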

Other observations

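All tests in this part were chosen after the data had been seen. Protein-coding genes with a reproduced peak in METTL16-KD and not in METTL3-KD were long, with a median span of 75.2 kb over 2546 genes, against 24.5 kb for the 404 genes with one in METTL3-KD alone and 40.4 kb for all protein-coding genes with a peak (permutation p = 0.0001, the smallest that 10000 permutations allow). Over all protein-coding genes with a reproduced peak the medians were 42.6 kb in METTL3-KD, 69.9 kb in METTL16-KD and 45.9 kb in WT. METTL3-KD genes as a whole were thus not short. Leaving out genes shared with the longer METTL16-KD lists removes long genes from the METTL3-KD set, so part of the gap is built in. Pseudogenes were over-represented in METTL3-KD, with a reproduced peak in 130 of 738 (17.6% against 14.0% of all genes, odds ratio 1.34; Fisher's exact test, adjusted p = 0.0049), and under-represented in METTL16-KD (odds ratio 0.599) and WT (odds ratio 0.554). Long non-coding RNA genes were under-represented in WT (odds ratio 0.418), METTL16-KD (0.436) and METTL3-KD (0.766, Fisher's exact test, adjusted p = 0.000514). The parts of their spans outside protein-coding spans nevertheless held a larger share of peak bases in METTL3-KD than in the other conditions. Protein-coding genes were over-represented in WT (odds ratio 2.44) and METTL16-KD (odds ratio 2.24) and showed no detectable departure in METTL3-KD (odds ratio 1.07, Fisher's exact test, adjusted p = 0.291).

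Reproduced knockdown peaks that shared no base on their strand with a WT list numbered 411 of 2597 (15.8%) in METTL3-KD and 276 of 10783 (2.56%) in METTL16-KD. Outside WT the METTL3-KD peaks of highest −log10 q in protein-coding genes lay over DDX5, the azurocidin gene AZU1 and ADGRE3. In METTL16-KD they lay over MYO15B (chromosome 17, 75626322 to 75626780), HFM1 and RAB11B, the last chosen after its values were seen. Of these genes AZU1 carried such a peak in both knockdowns, at 827923 to 830489 on chromosome 19 in METTL3-KD and 827856 to 830526 in METTL16-KD.

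Each knockdown list met the WT list of its own letter more often than the other WT list: 69.6% against 57.6% for METTL3-KD A, 85.9% against 75.1% for METTL3-KD B, 93.9% against 85.3% for METTL16-KD A and 94.8% against 88.0% for METTL16-KD B. Unequal WT list lengths would favour the same WT list for both letters, and the lowest same-letter excess was 6.79 percentage points. A candidate explanation is that 1 library enters every list of a letter: peaks with both ends identical numbered 13.0 to 81.7 per 1000 overlapping peaks in the 6 same-letter pairs of lists, against at most 0.490 in pairs of different letters between conditions. WT A and WT B, which share the DMSO library by label, gave only 1.41, so sharing that library gave few identical ends in this pair. Its role in the peak calling is not given, so the pair does not tell which kind of sharing would give many. The knockdown lists may still share a library with the WT list of their letter, and their overlaps with WT and with each other would then be partly built in. A shared culture batch with separate libraries cannot be told apart from this, because the labels give no batch.

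METTL3 had peaks in the METTL3-KD lists alone. Loss of the METTL3 transcript in the knockdown is a candidate explanation if those lists set a wild-type library against a METTL3-depleted one; METTL3 was 1 of 78 among 1753 genes with a reproduced METTL3-KD peak (4.45%) that had no peak in the other 4 lists, and the peak in B was weak, so the pattern is not specific to METTL3. METTL16 did not show it, with 5 peaks in METTL16-KD A and 0 in B, beside peaks in both WT lists.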
